A study of Mus musculus with 6 samples.

How the data were processed

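RNA was sequenced from cells recovered by bronchoalveolar lavage (BAL), a wash of the airspaces, from wild-type C57BL/6 mice aged 8 to 12 weeks. The study gave male and female mice cadmium chloride at 100 ng/kg or saline into the trachea and collected the lavage on day 7. The labels used here name 6 libraries (CD170, CD171, CD174, CD176, CD177 and CD178) but give none of them an exposure or a sex, so no library was assigned to a group. Library names are titles and not surface antigens.

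The deposited table holds raw read counts per gene, whole numbers that the authors did not normalize. Per the submitters' processing notes, the tools were bcl2fastq 2.18.0.12, Trim Galore 0.6.2, STAR 2.7.1a and HTSeq 0.11.2, with genome build GRCm38. The annotation release, the strand setting and other parameters are not given in the sources used here. Gene IDs were matched to GENCODE M21, which is on GRCm38: 48435 of 48795 IDs matched when the version was ignored, and 41427 had the same version. Symbols and coordinates come from that annotation. The 5 summary rows that name no gene were kept out of library sizes. They took 18.8% (CD177) to 46.0% (CD174) of all counts. Reads in no annotated feature took 25.0% in CD174, 16.6% in CD171 and 6.49 to 7.29% in the other libraries. Ambiguous reads took 9.99% in CD174 and 5.48 to 6.78% in the others. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies, such as the globin pairs and the Ear genes, are uncertain individually.

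Library sizes were scaled by the trimmed mean of M-values (TMM) in edgeR 4.0.16 under R 4.3.3. Library-size-scaled read counts (CPM) and log2 CPM with a prior count of 2 were computed from the deposited counts. Genes with at least 10 counts in at least 3 libraries were kept, which left 12627. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Because no library had a group, no differential expression test was run, and values are given per library or as median and range.

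The following were fixed before the data were examined. There were 29 gene lists, covering alveolar, recruited and profibrotic macrophages, alternative and classical activation, neutrophils, T, NK and B cells, dendritic cells, eosinophils and mast cells, red cells, platelets, epithelium, endothelium and mesenchyme, metal, oxidative and heat shock responses, fatty acid oxidation, glycolysis, mitochondrial-encoded genes, the mevalonate pathway, proliferation, interferon response, MHC class II, the BCL2 family, immediate early genes, nuclear and rRNA-linked transcripts and sex-linked genes. A list's level was its summed CPM, with an exact 95% Poisson interval. Its spread was the median over members of the log2 CPM range between libraries, and its coherence was the mean pairwise correlation of members. Both were placed among 10000 random lists matched on mean expression in 20 bins, and percentile 95 was taken as high. Genes were named by rule: the 10 with the highest median CPM, the 20 with the largest log2 range at a median CPM of at least 10, the 5 with the smallest range at a median CPM of at least 100, the 3 most abundant members of each list, the sex-linked list, and Mt1, Mt2 and Slc30a1. Any other gene named was chosen after its values were seen.

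Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A count of 0 allows up to 3 counts, which is 0.123 CPM in CD178 and 0.447 CPM in CD174. Gene ranges were compared with 20 sets of Poisson counts drawn at the real depths. The list measures were tested on simulated data for 12627 genes, of which 200 were given a range of 1, 2 or 3 on the log2 scale; the median recovered ranges were 1.31, 2.11 and 3.08, and the share of planted genes with a range of at least 1 was 80.0% at the smallest size. Of 40 random lists per simulation, 0, 3 and 1 passed percentile 95 for spread, and 4, 2 and 5 for coherence. Alternatives were DESeq2 1.42.0 size factors, total counts, no filter, a prior of 0.5, other measures of spread and correlation, and leaving out each library. Leaving out CD171 and CD174 together, and shares of counts without Lars2 or with CT010467.1, Gm26917 and Gm23935 also left out, were added after seeing the data.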

Results

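The 6 lavage libraries held between 7732244 gene counts in CD174 and 23599369 in CD178, with 18564880 in CD170, 12910428 in CD171, 14734261 in CD176 and 19447549 in CD177. The study asks how airspace cells differ after cadmium or saline. None of the 6 libraries carries an exposure label here, so that comparison was not analysed, and the libraries are described one by one. All 15 pairs differed by more than sampling noise, with a chi-square per degree of freedom of 17.2 or more, so none was treated as the same library deposited again. This comparison does not show whether any of them share an animal.

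Transcripts of alveolar macrophages, the resident phagocytes of the airspace, were abundant in each library. The alveolar macrophage list summed to between 31833 CPM (95% interval 31736 to 31930) in CD171 and 38722 CPM (38637 to 38808) in CD177. Chil3, a chitinase-like protein (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564, GRCm38), ranged from 17613 to 23678 CPM. Lpl, lipoprotein lipase, ranged from 2801 to 3603 CPM, and Ear2, an eosinophil-associated ribonuclease, from 2013 to 3045 CPM. Lyz2, a lysozyme of myeloid cells, was the most abundant gene by median, at 28159 to 38740 CPM. Other genes among the 10 most abundant were Tmsb4x (7946 to 13540 CPM), Actb (8372 to 12317 CPM), Fth1 (7850 to 16712 CPM), Psap (5866 to 8045 CPM) and mt-Co1 (2188 to 6344 CPM). The alveolar macrophage list had a median log2 range of 0.51, at percentile 19.1 of matched random lists; the percentile was 61 with total counts, 56.4 without CD174 and 8.4 without CD171.

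The recruited, profibrotic and alternative activation lists were lower. Their sums each varied less than 1.5-fold, while 11 of 13, 6 of 12 and 3 of 6 measured members had a log2 range of at least 1. The recruited monocyte and macrophage list summed to 534.0 CPM in CD171 and 756.9 CPM in CD176. Its sum came mostly from Csf1r at 267.3 to 396.9 CPM, Cd14 at 94.6 to 197.8 CPM and Fcgr1 at 42.1 to 113.1 CPM. Its members Ly6c2, Plac8 and F13a1 had at most 10 counts in any library, while Ccr2 lay between 10.5 and 22.2 CPM. The sum alone therefore does not show recruited cells. The profibrotic macrophage list lay between 2975 CPM in CD171 and 4402 CPM in CD170, and its member Fn1, fibronectin, between 482.8 and 1258 CPM. The alternative activation list lay between 1835 and 2162 CPM, with Mrc1, the mannose receptor, at 1420 to 1739 CPM.

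Markers of other leukocytes were low. The neutrophil list summed to 102.8 CPM in CD170 and 134.8 CPM in CD177, mostly from Ltf, Csf3r and Mmp8. Ly6g had 0 counts in each library, which allows at most 0.447 CPM in the shallowest. Its members S100a9, Ngp, Camp, Mpo and Elane had at most 11 counts in any library. S100a8 lay between 5.62 and 13.8 CPM and Cxcr2 between 3.61 and 8.83 CPM. The T cell list summed to 5.68 to 13.8 CPM, the B cell list to 1.23 to 3.28 CPM and the dendritic cell list to 25.3 to 37.5 CPM. The NK cell list reached 1.07 CPM, the eosinophil and mast cell list 2.79 CPM and the platelet list 2.81 CPM. The endothelium and mesenchyme list lay between 1.43 CPM in CD170 and 10.96 CPM in CD171.

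**Figure D1:**
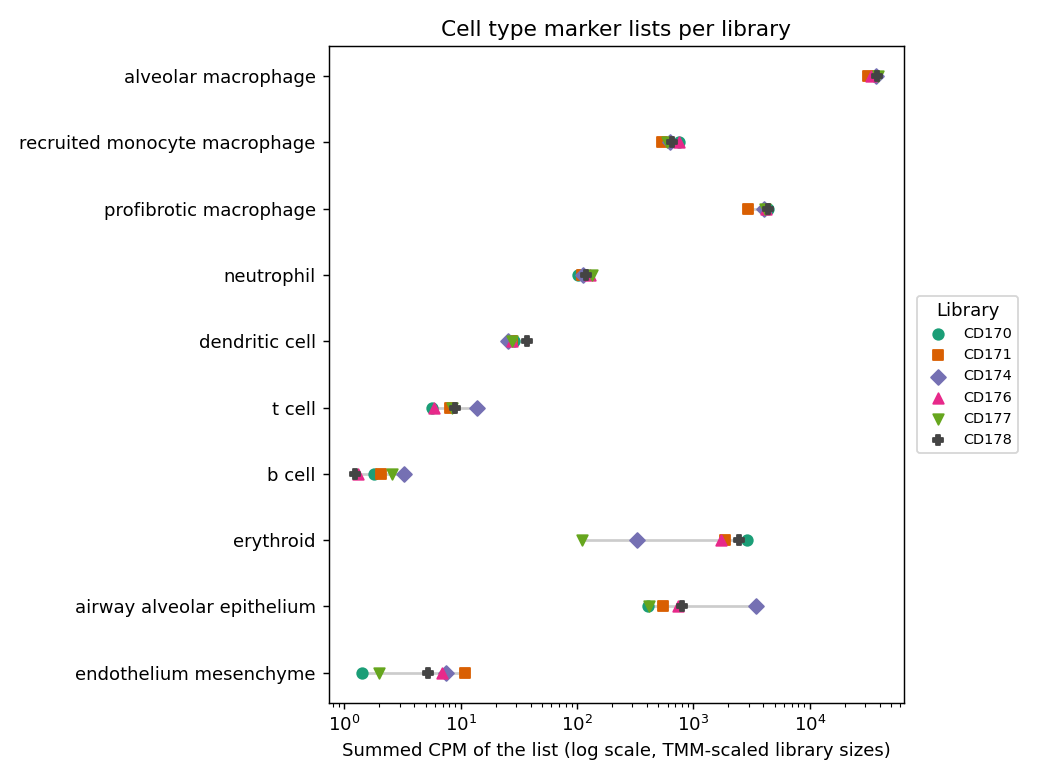
Summed CPM of cell type marker lists on a log axis, 1 point per library and a line from lowest to highest. The erythroid list runs from 111.2 to 2884 CPM and the epithelium list from 407.3 to 3467 CPM, while the alveolar macrophage list stays between 31833 and 38722 CPM.

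Red cell and epithelial transcripts differed several-fold between libraries. The erythroid list summed to 2884 CPM (95% interval 2860 to 2908) in CD170 and 111.2 CPM (106.7 to 115.9) in CD177, a ratio of 25.9, and its 5 measured members each had a log2 range of at least 1. Hbb-bs, an adult beta globin, ranged from 64.0 to 1714 CPM. The epithelium list reached 3467 CPM (3423 to 3512) in CD174, against 801.8 CPM in the next highest library and 407.3 CPM in the lowest. Sftpc, surfactant protein C of alveolar type 2 cells, was at 1602 CPM in CD174 and 254.1 CPM or lower elsewhere. Scgb1a1, the secretoglobin of club cells, was at 963.3 CPM in CD174 and 121.4 CPM or lower elsewhere. Epcam, also in this list, lay between 168.0 and 229.2 CPM.

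The metal response list summed to 1587 CPM (95% interval 1557 to 1617) in CD174 and to between 641.5 and 824.9 CPM in the other libraries. The spread of its 9 measured members lay at percentile 78.4. Without Mt1 the list summed to 321.2 CPM in CD174 and 286.6 to 367.8 CPM elsewhere. Mt1, a metallothionein that binds metal ions (ENSMUSG00000031765, chromosome 8, 94179082 to 94180327), was at 392.8 CPM in CD170, 457.2 in CD171, 1266 in CD174, 387.5 in CD176, 323.2 in CD177 and 370.5 in CD178. Mt2, also a metallothionein, was at 12.95 CPM (87 counts) in CD174 and 0.849 to 4.06 CPM elsewhere, and Slc30a1, a zinc exporter, lay between 10.2 and 16.9 CPM. The oxidative stress list summed to 4143 CPM in CD174 and 2735 to 3089 CPM elsewhere. Its members Hmox1, heme oxygenase 1, and Prdx1, a peroxiredoxin, were at 569.9 and 2066 CPM in CD174. Without these members the list summed to 1507 CPM in CD174, 1499 CPM in CD170 and 1204 to 1287 CPM in the others. CD174 was also the library with the highest epithelium list. It had the highest share of counts in 4 genes chosen after their values were seen, at 10.8% with Lars2 and 6.97% without it. These were CT010467.1, annotated as rRNA, its neighbour Gm26917, and Lars2 and Gm23935 on other chromosomes.

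The heat shock list lay between 2071 CPM in CD178 and 3670 CPM in CD176, with Hspa8 at 1661 to 3034 CPM. Immediate early genes summed to 601.9 CPM in CD171 and 1344 CPM in CD176, and classical activation genes to 79.0 CPM in CD171 and 217.9 CPM in CD176. Il1b, an inflammatory cytokine, was at 104.8 CPM in CD176 and 20.7 to 38.1 CPM in the others. The MHC class II list ranged from 2048 to 3179 CPM, the interferon list from 135.5 to 254.8 CPM and the BCL2 family list from 1090 to 1563 CPM. The proliferation list lay between 686.4 CPM in CD176 and 1290 CPM in CD174, with Mki67 at 51.3 to 155.9 CPM.

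Fatty acid oxidation genes summed to 1883 to 2106 CPM and glycolysis genes to 4694 to 5516 CPM, and 1 and 3 of their 13 measured members had a log2 range of at least 1. The mevalonate list lay between 735.9 CPM in CD171 and 1182 CPM in CD176, a ratio of 1.61. Mitochondrial-encoded genes ranged from 3811 CPM in CD171 to 14821 CPM in CD178; mt-Co2, mt-Co3, mt-Atp6 and mt-Nd4l had at most 6 counts in any library, so the level of this list is uncertain. The nuclear and rRNA-linked list ran from 2574 CPM in CD177 to 44774 CPM in CD174, mostly from Lars2, at 1997 and 43705 CPM in these libraries.

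**Figure D2:**
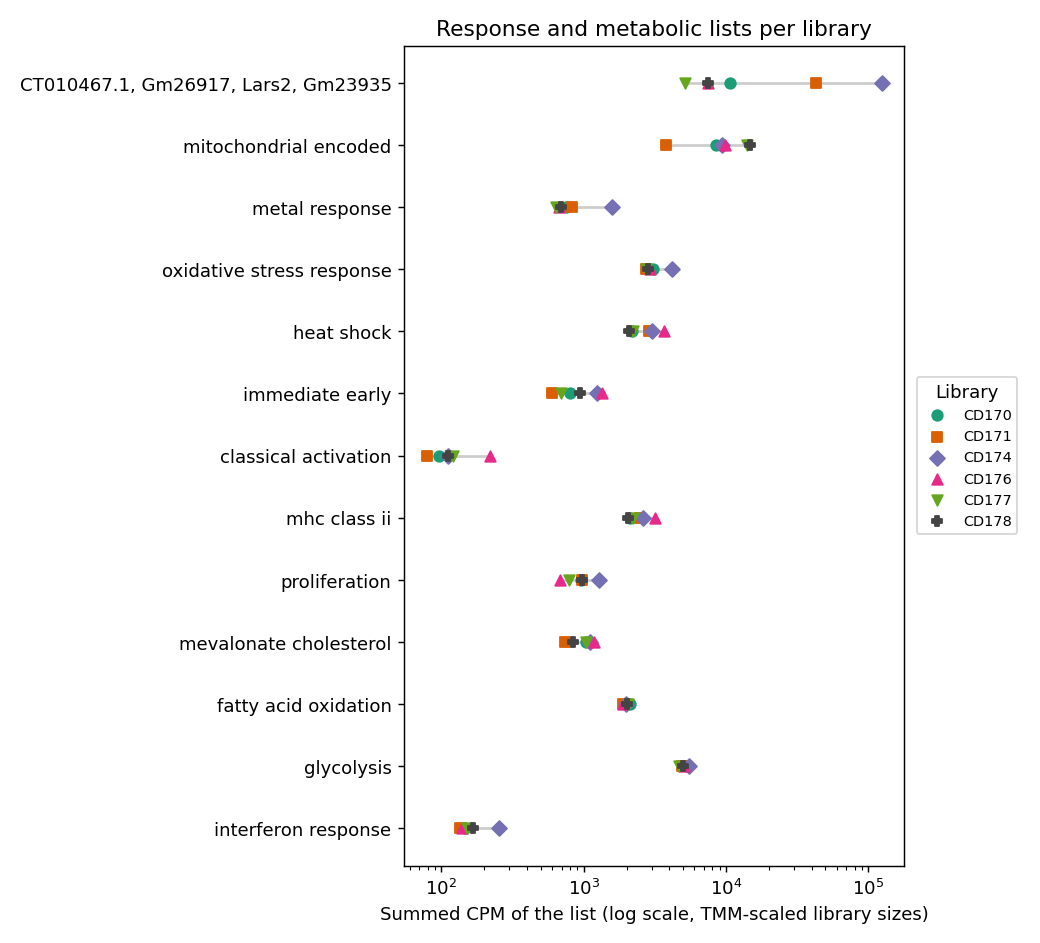
Summed CPM of response and metabolic lists on a log axis, 1 point per library and a line from lowest to highest. CD174 is highest for the metal list at 1587 CPM and the oxidative list at 4143 CPM, and CD176 for the heat shock list at 3670 CPM.

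Of 24 lists with at least 3 measured members, 7 had a spread at or past percentile 95. Lists of genes drawn independently would give 1.2. Members of many of these lists were correlated, so 1.2 is not their own chance rate. The passing lists were the erythroid, epithelium, mitochondrial-encoded, immediate early and nuclear and rRNA-linked lists (each at percentile 100.0), classical activation (99.9) and proliferation (99.7). In the nuclear and rRNA-linked list, Lars2 and Gm26917 had log2 ranges of 4.45 and 4.4. Neat1 and Malat1 in that list had log2 ranges of only 0.89 and 0.39. Coherence passed in 11 lists, and 6 passed both. Without CD171 and CD174, 22 lists had at least 3 measured members and 13 of them passed for spread. Of the 26 lists with more than 3 counts in each of the 6 libraries, 10 differed at least 2-fold in level between libraries, and 4 did without CD171 and CD174. With the count minimum applied to the 4 remaining libraries alone, 7 of 29 lists did, the NK cell, eosinophil and mast cell, and platelet lists included.

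Among the 12627 filtered genes, 6376 (50.5%) had a log2 range of at least 1 and 3176 (25.2%) of at least 2, against Poisson means of 743.4 and 42.5. CD174 was the lowest library for 1533 of the 3176 and the highest for 963. Without CD171 and CD174 the counts were 2067 and 471. Als2cl, Alkbh3 and Mfsd8 had 0 counts in CD174 and between 8.72 and 17.4 CPM in the others. The steadiest abundant genes included Atp5b, a subunit of ATP synthase, at 946.6 to 1018 CPM, and Slc25a11 at 119.9 to 130.6 CPM.

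Xist, the RNA of the inactive X chromosome, was at 0.212 CPM in CD170, 0.0772 in CD171, 195.1 in CD174, 235.4 in CD176, 293.0 in CD177 and 261.0 in CD178. Ddx3y, on the Y chromosome, was at 87.4 CPM in CD170 and 93.1 CPM in CD171, with 0 counts in the other libraries. Uty, Kdm5d and Eif2s3y likewise had counts in CD170 and CD171 alone.

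**Figure D3:**
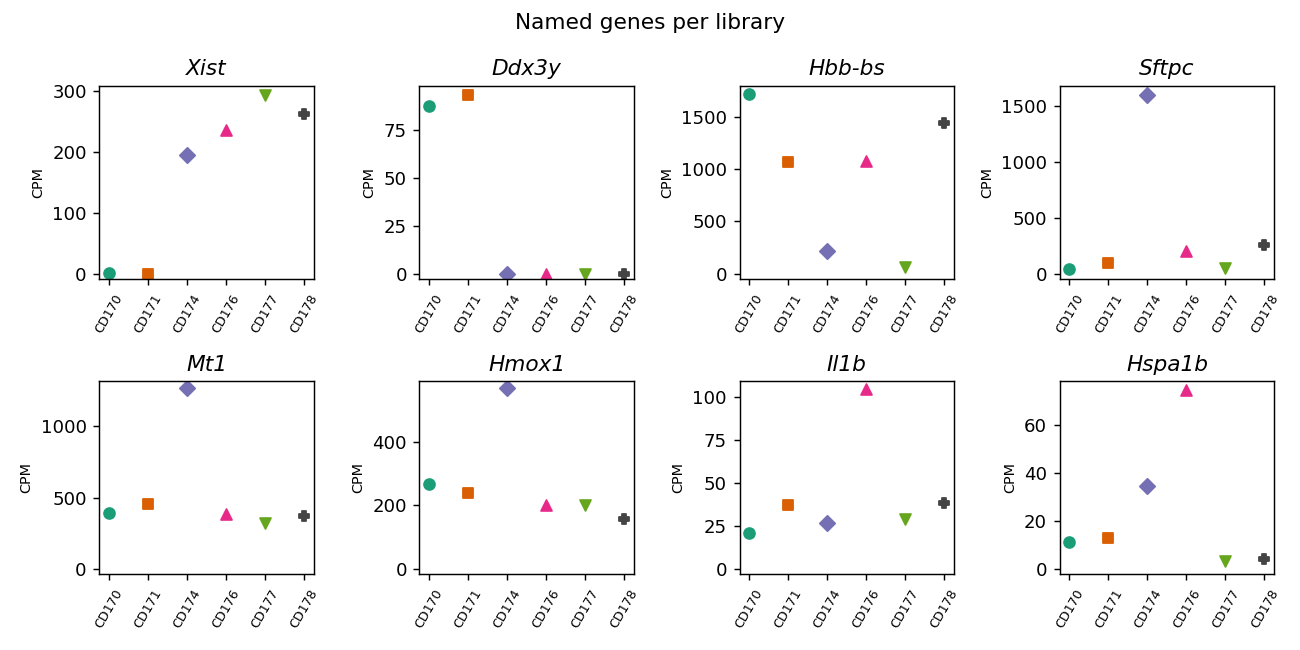
CPM of 8 named genes, 1 point per library, each panel starting at or just below 0. Sftpc and Mt1 are highest in CD174, at 1602 and 1266 CPM, and Hbb-bs is lowest in CD177, at 64.0 CPM.

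The libraries also differed in content at the level of whole profiles. The 10 most counted genes took 20.9% (95% Wilson interval 20.8 to 20.9) of counts in CD174 and 11.1 to 13.2% in the others. Without CT010467.1, Gm26917, Lars2 and Gm23935, the 10 most counted of the remaining genes took 13.3% in CD174 and 11.1 to 12.0% in the others. Thinned to 7732244 counts, the libraries had between 13398 genes in CD174 and 16876 in CD178. Of the genes for which the other 5 libraries predicted at least 20 counts, 147 had 0 in CD174, 70 in CD171, and 5 to 26 in the other libraries. The first principal component held 59.4% of the variance.

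**Figure D4:**
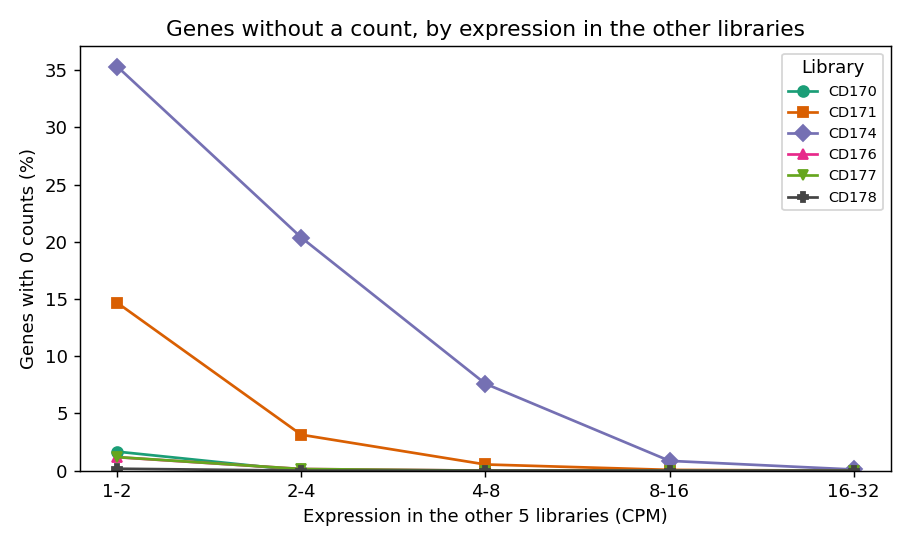
Percent of genes with 0 counts in each library against expression in the other 5 libraries, in bins of CPM. In CD174 the share falls from 35.3% in the lowest bin to 0.100% in the highest.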

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

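Tests of shallow sequencing, scatter, short transcripts, scaling and the Sftpc comparison were chosen after the results were seen, as were their thresholds; those of few molecules, transcript length of missing genes and held-out epithelial genes were written before. Of 129 values examined over the 6 libraries, 30 had a highest or lowest library whose gap exceeded Dixon's 95% critical ratio, and 24 of the 30 were in CD174. Chance marks about 1 in 20 groups, but that rate does not apply to this set: 9 of the 30 are among 20 genes named for a large range, and list sums stand beside their own members. Of 26 list sums, 7 were past the ratio, 4 of them in CD174. No effect of exposure or sex was tested, since no library has a group.

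CD174 was highest for the epithelium list (3467 CPM), the metal list (1587 CPM), the oxidative list (4143 CPM) and the interferon list (254.8 CPM). Its 10 most counted genes took 20.9% of counts (13.3% without CT010467.1, Gm26917, Lars2 and Gm23935), and these 4 genes 10.8% (6.97% without Lars2). Protein-coding genes, Lars2 included, took 91.3%, the lowest share (98.1% of the counts outside the 4 genes). Single genes highest there were Fth1 (16712 CPM), Ctss (6529), Cxcl15 (82.3), Sftpa1 (216.1), Sftpc (1602), Scgb1a1 (963.3), Mt1 (1266), Prdx1 (2066), Hmox1 (569.9), Bst2 (87.4) and H2-DMa (480.7). Genes lowest there were Als2cl (0 CPM), Alkbh3 (0), Sepsecs (0.149), Zfp128 (0.149), Fgfr1op (0.149) and Srbd1 (0.298). CD171 was lowest for the profibrotic list (2975 CPM) and Gapdh (725.8 CPM). CD176 was highest for classical activation (217.9 CPM) and Il1b (104.8 CPM), CD178 for the dendritic cell list (37.5 CPM) and CD170 for Tgfb1 (560.9 CPM).

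The genes without counts in CD174 numbered 147, although Poisson sampling at its depth gives about 1.3e-07, which argues against shallow sequencing. A library made from few RNA molecules may account for them. The rate at which the share of missing genes fell with expression varied 2.42-fold across expression bins, within the factor of 3 set beforehand. However, that rate declined steadily, and a constant one was the simplest form of the model. The rule does not set CD174 apart. Between its lowest and highest bins with a rate, it went from 1.34 to 0.629 per CPM in CD171, 3.04 to 2.27 in CD176 and 2.99 to 2.29 in CD177, also within that factor. Missing genes had transcripts 1.22 times as long as matched genes (1.06 to 1.38). That ratio lay in the range set beforehand for no length effect, but its interval reached past that range. The whole interval stayed under the ratio set for a length effect, so only a smaller effect of length stays open.

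Surfactant and secretoglobin transcripts in CD174 may come from epithelial material in the lavage. A separate list of 24 epithelial genes, picked without looking at their values, had a median log2 ratio of 1.16 for CD174 over the median of the other libraries, with 20 above 0. That median lay at percentile 100.0 of matched lists, which argues against random scatter.

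Mt1, Hmox1 and Prdx1 were picked for being high in CD174, so their own percentiles among random lists (99.96 on expression, 99.9 also on length) decide nothing, nor do those of the 23 fixed metal and oxidative genes that hold them (median log2 ratio 0.62, percentiles 99.99 and 100.0). Without the 3 genes the other 20 had a median of 0.21 with 13 above 0, at percentiles 93.61 and 97.2. The top 3 of the 23 lay at 91.14 and 90.06 of the top 3 of random lists. Values matched on expression alone were under percentile 95, the rule for scatter of a library made from few molecules. Random lists carry every kind of difference in CD174, so these percentiles do not exclude scatter but cannot single it out. Short transcripts stay open. TMM, DESeq2 size factors and total counts moved the median gene by 0.28, while the log2 ratio stayed at 1.46 to 1.74 for Mt1, 1.22 to 1.52 for Hmox1 and 0.42 to 0.69 for Prdx1, each above the next library, which argues against scaling as the whole cause, although the other 20 genes had medians of only -0.03 to 0.24. Epithelial material could also bring these transcripts and stays open: CD178, second in Sftpc, differed from CD170 by 76.23 CPM for Prdx1, -22.29 for Mt1 and -112.4 for Hmox1, where 101.5, 119.7 and 50.03 were needed, a shortfall of at least 0.117 ranges over the other 5 libraries, but 2 libraries and an assumed profile exclude nothing. The tests of this pattern were revised several times after values were seen, and the pattern is a hypothesis at most.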

How the results depend on the processing

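No paired analysis was possible because no library has a group. DESeq2 size factors left the counts of lists and genes within 1.5 times their main values. With total counts, coherence passed in 7 lists. Without the filter, 13820 and 7203 genes had a log2 range of at least 1 and 2, as more genes were examined, and the first component held 45.9%. Leaving out 1 library at a time gave 7 to 12 of 24 lists (of 23 without CD178) past the spread threshold, 10 to 14 for coherence, 7 to 10 with a 2-fold level difference, 3862 to 5826 and 1449 to 2772 genes with a range of at least 1 and 2, and 58.1 to 78.0% for the first component; CD174 moved the spread and gene counts most. Without CD171 and CD174, added after seeing the data, these were 13 of 22 lists, 2067 and 471 genes, and 4 of 26 lists with a 2-fold level difference, or 7 of 29 when the count minimum was applied to the 4 remaining libraries alone. From summed CPM, 0 relations had an adjusted exact permutation p under the threshold, where 1 did from mean log2 CPM. Relations of the alveolar macrophage list changed sign with neutrophils (0.18) and fatty acid oxidation (0.81) from summed CPM, and without the 2 libraries farthest from the median with recruited (-0.76) and profibrotic macrophages (-0.48), epithelium (-0.34), fatty acid oxidation (0.21) and mevalonate genes (-0.98). Apart from the filter, the cause was not tested. Lists summing to a few CPM, such as NK and B cells, are limited by depth.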

Other observations

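All tests in this part had thresholds set after gene values had been seen; the pairs of lists were fixed before. Sema3e, a semaphorin, was at 0.424 CPM in CD170, 0 in CD171, 34.1 in CD174, 15.2 in CD176, 19.8 in CD177 and 10.3 in CD178. It is among the genes with the largest range, and its 2 lowest libraries are those with Y-linked counts; no test was made. Inmt was at 11.4 CPM in CD170, 1.16 in CD171, 10.9 in CD174, 52.4 in CD176, 5.71 in CD177 and 42.7 in CD178.

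Lars2, a mitochondrial synthetase gene, was at 43705 CPM in CD174 and 18236 CPM in CD171, and its ratio to CT010467.1, annotated as rRNA, stayed between 0.769 and 1.13 over the 6 libraries. Its log2 ratio in CD174 was 3.86, above the -3.53 to 1.17 of 16 other mitochondrial synthetases. Whether these counts are reads of ribosomal RNA was not tested.

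On the first principal component CD174 scored 137.2 and the others -33.5 to -19.3; on the second (23.0% of variance) CD171 scored 84.0 and the others -26.0 to -4.9.

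Globin transcripts may reflect red cells or their RNA in the lavage: the Alas2 to Hbb-bs ratio varied 1.67-fold while Hbb-bs varied 26.8-fold. Whether white blood cells came along cannot be told apart with 6 libraries, since the neutrophil and erythroid sums had a Spearman rho of -0.71 (exact permutation p = 0.136). The neutrophil sum also came mostly from Ltf, Csf3r and Mmp8, while Ly6g had 0 counts, so it may not follow neutrophils. This pattern was weighed first and then gave way to that of Mt1 after values were seen.

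Of 10 planned relations between lists over the 6 libraries, 1 had a Benjamini-Hochberg adjusted p under the threshold by a two-sided exact permutation test. The metal and oxidative lists had a Pearson r of 0.99 (exact permutation p = 0.0014, the smallest possible, adjusted 0.014) and a Spearman rho of 1.0 (exact permutation p = 0.0028, adjusted 0.028), with r 0.91 without CD174 and CD177. From summed CPM, r was 0.93 (exact permutation p = 0.0708, adjusted 0.315) and Spearman rho 0.6 (exact permutation p = 0.2417, adjusted 0.594). The relation of the metal and oxidative lists therefore depends on the summary. Members were also weakly correlated within each list. Their mean pairwise correlation was 0.07 (percentile 81.0) in the metal list and 0.16 (percentile 97.1) in the oxidative list. The alveolar macrophage list had r of -0.16 with neutrophils, 0.29 with recruited macrophages, 0.51 with profibrotic macrophages, 0.27 with epithelium, 0.69 with T cells, -0.23 with fatty acid oxidation, 0.22 with mevalonate genes, 0.16 with proliferation and 0.51 with library depth. Adjusted exact permutation p for these ranged from 0.743 to 0.815 for r and from 0.292 to 0.919 for Spearman rho, and 6 libraries leave each of them open.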
